A study of Arabidopsis thaliana with 18 samples.

How the data were processed

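Gene expression was measured on 18 one-colour (Cy3) Agilent microarrays of whole Arabidopsis thaliana plants, 3 arrays for each of 6 groups. The groups were set by the sample labels: 3 genotypes (a line labelled as overexpressing bHLH112, an insertion line of the SALK collection in the same gene, and wild type Columbia), each given water or 150 mM NaCl for 3 h. Per the labels the replicates came from independent experiments with different plants, and replicate numbers pair no samples.

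For each array the authors deposited the scanner table, made with Agilent Feature Extraction 10.7.1.1. Its processed signal is, per the file headers, an intensity after background subtraction and detrending, with no normalization between arrays. A value table of the whole series was deposited too. In its 12 overexpressor and SALK columns the deposited values were log2 signals with equal quantiles (column medians 8.16), which correlated with the log2 processed signal of the same array at r of 0.998 or above. Its other 6 columns, those of wild type, were equal to the background pixel standard deviation of the same array and were not used.

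The file headers place the arrays on 5 slides scanned in 2 sessions. All 12 arrays of the overexpressor and the SALK line were scanned in the first session and all 6 wild type arrays in the second, over a year later. A difference between a line and wild type therefore cannot be told apart from a difference between sessions, including plants or harvests that went with them. The salt response of each genotype, and the comparison of both lines with each other, lie within a session. A difference between salt responses cancels any session effect that adds equally to water and salt arrays.

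Log2 of the processed signal was averaged over the spots of a probe that the scanner software did not mark as non-uniform or as population outliers, and the array's 75th percentile was subtracted. A probe was kept if it was well above background on all 3 arrays of at least 1 group, which left 33934 of 43603 probes. Each gene was represented by its brightest kept probe, giving 25173 features, of which 21678 had a locus and 3495 were probes without one. Depth is given by the probes well above background, 29774 to 35052 per array, and the number of arrays limits the precision. No spot was saturated.

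A model of the 6 group means was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (12 residual degrees of freedom), and 11 comparisons were tested with its moderated test, two-sided. P values were adjusted by the Benjamini-Hochberg method over all features within a comparison, and an adjusted p under 0.05 was called. Errors of fold changes are standard errors of this fit. Where no array of the dimmer group had a probe well above background, the dimmer arrays were set to the lowest signal that their array held well above background, and the fold is given as at least that number.

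Before the data were examined, 18 gene lists were fixed from textbook knowledge, as were the comparisons, the named-gene rule and all alternatives save those restricted to a slide and the lists without 1 array. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 18 lists of a comparison, and again with an estimated correlation. In the 7 comparisons made within a session or between salt responses, 44 of 126 list tests were called and 5 of these with an estimated correlation. In the 4 comparisons of a line with wild type, 38 of 72 were called and 4 with an estimated correlation. Counts adjusted over the list alone use the p values of the list's members only.

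Named genes followed a rule: bHLH112 in every comparison, then the 6 largest increases and 6 largest decreases among called genes that had a symbol and whose arrays did not overlap between groups (for differences of salt responses, the call alone), and from each list up to 4 called members with the largest changes. On simulated arrays with each gene's residual spread and independent errors, 200 genes were changed per comparison. The simulation had no slide effects, no correlation between genes and the same spread on all arrays. The following rates thus need not carry over. Between 23.9% and 58.2% of the 2-fold changes, between 58.2% and 86.6% of the 4-fold changes and between 81.8% and 93.9% of the 8-fold changes were recovered, and 2% to 8.39% of calls were false. In 1 simulated list test, the shifted list was called, and so was 1 of the others.

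The alternatives were normexp background correction with an offset of 50, quantile normalization, no filter, the mean of a gene's probes, the authors' value table, slide as a fixed or as a random block, the replicate number as a block, limma's trend and robust options, a fit to only the groups compared, a minimum of 2-fold, and leaving out each array in turn. A session term could not be fitted, since it equals wild type against the other genotypes. With slide as a fixed block, each salt response rests on 1 slide, with 1 array of a treatment against 3 of the other.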

Results

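Whole 4-week-old Arabidopsis plants of 3 genotypes were compared after 3 h of watering with or without 150 mM NaCl, with 3 arrays in each of the 6 groups. The purpose stated by the labels is to find genes whose expression changes in plants with raised or lost expression of bHLH112, a basic helix-loop-helix transcription factor, under normal and salt conditions. On each array 68.3% to 80.4% of the probes were well above background. Arrays of 1 group correlated with each other at r between 0.934 and 0.991 across genes. The first principal component (45.3% of the variance) separated the 6 wild type arrays, scanned in their own session, from the other 12. Along the second component (20.7%), overexpressor water replicates 1 and 3 lay highest of all arrays, at 126 and 132, and replicate 2 at -3.48. Values after ± are standard errors with n = 3 arrays per group, changes of lists are medians of log2 fold changes, and adjusted p values are those of limma over all genes unless said otherwise.

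The level of bHLH112 (AT1G61660) was read by 2 probes on chromosome 1. The probe in the fit (positions 22757586 to 22757645 by the array files) had a mean log2 level in water of 1.07 ± 0.04 (SD) in wild type. It was 0.65 ± 0.26 in the overexpressor and -2.72 ± 0.08 in the SALK line (n = 3 each). The SALK line was 13.8-fold below wild type in water (log2 -3.79 ± 0.17, adjusted p = 3.26e-09) and 7.43-fold below it in salt (log2 -2.89 ± 0.17). The line labelled overexpressor was not above wild type in water: its log2 difference was -0.43 (adjusted p = 0.0464, and up to 0.191 without overexpressor replicate 1). That call was also lost without overexpressor replicate 3 (adjusted p = 0.0798) and without wild type replicates 1, 2 or 3 (0.0841, 0.107 and 0.0816). In salt the overexpressor was 1.59-fold above wild type (log2 0.67, adjusted p = 0.00506). Against the SALK line it was higher by 3.37 in water and 3.56 in salt on the log2 scale. With salt, bHLH112 rose in the overexpressor (log2 0.66 ± 0.17, adjusted p = 0.0382). Its differences of -0.44 in wild type (adjusted p = 0.142) and 0.46 in the SALK line (adjusted p = 0.225) did not pass the test. The call in the overexpressor was lost without any array but water replicate 2. Adjusted p was 0.12 and 0.0926 without water replicates 1 and 3 and 0.0605, 0.101 and 0.122 without salt replicates 1, 2 and 3. The second probe (positions 22758869 to 22759024) was dimmer in all groups and gave -0.65 ± 0.27 for the overexpressor against wild type in water, 0.67 ± 0.27 in salt, and -0.90 ± 0.27 and -1.15 ± 0.27 for the SALK line. For the overexpressor against the SALK line it gave 0.25 ± 0.27 in water (adjusted p = 0.479 over all probes) and 1.82 ± 0.27 in salt (0.000605), so the probes disagreed in water.

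**Figure D1:**
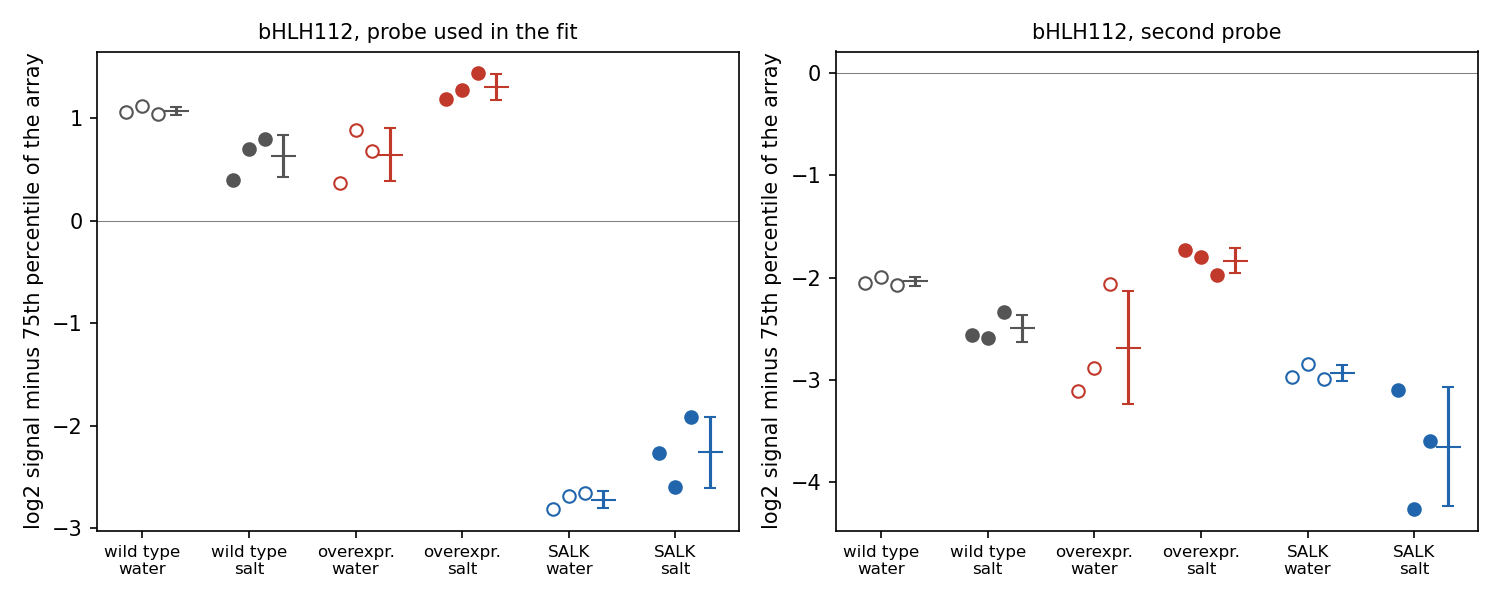
Log2 signal of the 2 bHLH112 probes minus the array's 75th percentile (y axis) in the 6 groups (x axis). Points are the 3 arrays of a group, open for water and filled for salt, and bars beside them are the mean and SD; in water the overexpressor mean was 0.65 and the wild type mean 1.07 on the probe in the fit.

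The salt response of wild type shows how unmodified plants reacted to 3 h of NaCl. In wild type, some genes of dehydration and of abscisic acid (ABA) signalling rose, and 24 of 41 early stress transcription factors fell. The largest increases were those of NIG1, a bHLH transcription factor (17.2-fold, log2 4.11 ± 0.36, adjusted p = 1.35e-05), GolS3, a galactinol synthase (10.9-fold), and TSPO, a membrane protein of the stress response (10.4-fold). They were followed by the dehydration gene RD29A (10.1-fold), HAI1, a protein phosphatase of ABA signalling (9.14-fold), and AT5MAT, an anthocyanin malonyltransferase (8.57-fold, its water probe above background on 1 of 3 arrays). The largest decreases were those of DDF2 (99.4-fold, log2 -6.63 ± 0.80, adjusted p = 0.000156) and DDF1 (43.7-fold), both DREB-type transcription factors. PHI-1 fell 38.7-fold, and the trehalose-6-phosphate phosphatase TPPI, the tetraspanin TET9 and the fasciclin-like arabinogalactan protein FLA3 fell 18.9-fold each (FLA3 above background on 1 of 3 salt arrays).

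Of the 24 measured ABA and dehydration effector genes, 6 rose and 1 fell in wild type (13 and 1 adjusted over the list alone), with a median of 1.32. A fit with slide as a fixed term gave a median of 0.71 and 0 called members by limma. RD29A (log2 3.33 ± 0.60) and ATHB7, a homeodomain factor (2.24 ± 0.46), were among them. In ABA synthesis, breakdown and core signalling, 12 of 32 rose and 4 fell (14 and 6 adjusted over the list alone, median 0.36). A fixed slide term gave 2 and 2 with a median of 0.12, and the list lost its call (adjusted p = 0.139). The phosphatase genes HAI2 and ABI2 rose by 2.99 and 2.45, and CYP707A3, an ABA 8'-hydroxylase that breaks ABA down, changed by -3.61 ± 0.33. Among 41 early stress transcription factors, 24 fell and 1 rose (28 and 2 adjusted over the list alone, median -1.69), such as the zinc finger gene ZAT7 (-4.14 ± 0.60). Of 22 auxin response genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone, median 0.46), with SAUR20 at 2.24 and SAUR21 at 2.04. Of 22 heat shock genes, 3 fell (6 adjusted over the list alone, median -1.07), including the repressor HSFB2B (-1.83 ± 0.15). The heat shock level was 2.77 in water replicate 1, 0.546 and 0.61 in water replicates 2 and 3 and -0.13, -0.028 and 0.555 in salt. Without water replicate 1 the list's median was -0.41 (adjusted p = 0.0368). Lower with a fixed slide term were 12 early stress factors and 1 heat shock gene, and higher 8 auxin response genes. Camera called these 5 lists (adjusted p from 2.08e-12 to 0.0128), each with adjusted p = 0.361 with an estimated correlation.

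Other lists were not called in wild type and held single changes. Jasmonate genes rose in 3 and fell in 5 of 28 (5 and 5 adjusted over the list alone), where the repressor genes JAZ8 and JAZ7 changed by -3.50 and -2.73. This list's median was 0.24, its mean -0.05 and its test pointed up. Of 22 salicylate and pathogen defence genes, 1 rose and 5 fell (1 and 5 adjusted over the list alone), with the glutaredoxin GRX480 at -2.49. Expansins and xyloglucan endotransglucosylases fell in 5 of 24 and rose in 1 (7 and 1 adjusted over the list alone), with XTH18 at -4.02 and XTH22 at -3.02. Sodium, potassium and proton transport genes rose in 4 of 20 (4 adjusted over the list alone), including the vacuolar exchanger NHX1 (1.15 ± 0.18). The list's median was -0.03, its mean 0.08 and its test pointed up. Of 20 root markers, FRO2, a ferric reductase, rose (1.45) and the nitrate exporter NAXT1 fell (-3.20), the same 2 members adjusted over the list alone. Among 15 morning clock genes 2 rose (4 adjusted over the list alone), RVE2 by 1.69. Of 19 aquaporins 1 rose and 1 fell (1 and 3 adjusted over the list alone), PIP1;4 by 1.80. No member of the 42 photosynthesis genes, the 12 flower markers or the 14 superoxide dismutases, catalases and ascorbate peroxidases was called, with list medians of -0.09, -0.31 and -0.13. Class III peroxidases fell in 2 of 29 (0 adjusted over the list alone by limma), with a median of 0.11, a mean of -0.12 and a test pointing down. Of 10 proline genes 1 rose (median 0.13). Of 11 evening clock genes 1 rose (median -0.07, mean 0.07, test pointing up). Both counts were unchanged adjusted over the list alone. In the salicylate list the median was -0.01, the mean 0.01 and the test pointed down. In the morning clock list the median was -0.02, the mean 0.20 and the test pointed up. Of these lists, with a fixed slide term, the morning clock list had 1 member higher, the salicylate, expansin, root and peroxidase lists 1 lower each, and limma called 0 in the others.

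In all, 2371 of 25173 genes were called in wild type, 1000 higher and 1371 lower. The count was 1248 without water replicate 3, 1330 without salt replicate 2 and 1257 without salt replicate 3. It was 3210 when only these 6 arrays were fitted. Single arrays ended the calls of HAI1 (salt replicates 2 or 3, adjusted p up to 0.0813), FLA3 (water replicate 3, salt replicates 2 or 3, up to 0.0804), AT5MAT (any but salt replicate 1, up to 0.164) and TPPI (any of the 6, up to 0.135).

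The same treatment was compared in the overexpressor, where 29 of 41 early stress transcription factors and 15 of 28 jasmonate genes rose with salt. RRTF1, an AP2/ERF factor of redox responses, rose at least 233-fold. DDF1 rose at least 51.1-fold and DDF2 at least 20.8-fold, since none of their water arrays was above background. ORA47, an AP2/ERF factor that activates jasmonate synthesis, rose 85.5-fold (log2 6.42 ± 0.65, adjusted p = 9.83e-05), the ubiquitin ligase PUB19 50.5-fold (water probe above background on 1 of 3 arrays) and the cold-response factor CBF1 28.6-fold. The largest decreases were those of the receptor-like kinase CRK30 (at least 8.22-fold), the ABA receptors PYL6 (7.67-fold, above background on 2 of 3 salt arrays) and PYL4 (6.50-fold). They also included the gibberellin-regulated GASA1 (4.84-fold) and the auxin-induced SAUR20 (4.2-fold). SAUR75 fell at least 3.64-fold and cannot be ranked among them.

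Of 41 early stress transcription factors, 29 rose and none fell in the overexpressor (34 and 0 adjusted over the list alone by limma), with a median of 2.09, or 2.05 with 5 dim members at their bound. Camera called this list (adjusted p = 1.42e-34, and adjusted p = 0.043 with an estimated correlation). Jasmonate genes rose in 15 of 28 and none fell (24 and 0 adjusted over the list alone, median 1.78), among them the repressor JAZ5 (3.45 ± 0.30). The list had adjusted p = 1.45e-19, and adjusted p = 0.0892 with an estimated correlation. Of 24 dehydration effector genes 7 rose (16 rose and 1 fell adjusted over the list alone, median 1.40, or 1.33 with dim members at their bound), with adjusted p = 0.372 with an estimated correlation. In ABA synthesis and core signalling 4 rose and 4 fell (11 and 5 adjusted over the list alone, median 0.31, adjusted p = 0.416 with an estimated correlation). HAI2 rose at least 5.97-fold and CYP707A3 rose 9.75-fold. In the proline list (median 0.34, adjusted p = 0.102 with an estimated correlation) 1 of 10 rose, 2 adjusted over the list alone. P5CS1, which makes the first intermediate of proline synthesis, rose 7.42-fold. Class III peroxidases (median 0.74, 1 of 29 called), aquaporins (0.40, 1 of 19), expansins and xyloglucan endotransglucosylases (0.26, 5 higher and 1 lower of 24) and root markers (0.45, or 0.42 at the bound, 1 of 20) were called too. They lost the call with an estimated correlation (adjusted p = 0.59, 0.433, 0.493 and 0.796). Adjusted over the list alone, these counts were 0, 1, 7 higher and 2 lower, and 0. Leaving out 1 array ended the call of the peroxidases (water replicate 1 or salt replicate 3, adjusted p up to 0.307), aquaporins (water replicates 1 or 2, salt replicates 1 or 3, 0.15), expansins and xyloglucan endotransglucosylases (water replicates 1 or 3, salt replicate 3, 0.245) and root markers (any water replicate or salt replicate 3, 0.709). Without water replicate 2 the ABA synthesis and core signalling (0.344) and proline (0.131) lists lost it too. A fixed slide term gave the peroxidases a median of 0.01, expansins and xyloglucan endotransglucosylases 0.13 and root markers -0.16, and these 3 lists lost their call (adjusted p = 0.436, 0.22 and 0.891). Root markers also lost it with normexp correction (0.105) and quantile normalization (0.0573). EXPA16 rose at least 4.80-fold and XTH22 7.52-fold. GRX480 (2.25) and HSFB2B (1.13) rose, each as a member of a list that was not called. In addition, 7 of 22 auxin response genes fell (7 adjusted over the list alone, median -0.08), SAUR21 by a log2 of -1.45 ± 0.28. That list was not called (adjusted p = 0.204, and adjusted p = 0.819 with an estimated correlation), and with a fixed slide term limma called 0 of its genes lower and 1 higher. The same term gave 16 early stress factors, 4 jasmonate genes and 1 proline gene higher, 1 higher and 2 lower in ABA synthesis and core signalling, and by limma 0 dehydration effector genes (median 1.25) and 0 aquaporins.

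The overexpressor had 1511 called genes, 865 higher and 646 lower. Thus 57.3% were higher, against 42.3% after quantile normalization. The count was 4551 without water replicate 2, 836 without water replicate 3, 723 and 904 without salt replicates 2 and 3, and 237 when only these 6 arrays were fitted. Water replicate 2 differed from replicates 1 and 3 in the level of photosynthesis genes (-0.077, against 0.478 and 0.680) and class III peroxidases (0.343, against -1.89 and -0.596). SALK water arrays lay near replicate 2 for photosynthesis (-0.051 to 0.027) but not for peroxidases (-1.635 to -0.216). Single arrays ended the calls of PYL6 and GASA1 (water replicate 3 or salt replicate 1, adjusted p up to 0.0706 and 0.0971) and SAUR75 (salt replicate 2, 0.0511).

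In the SALK line the decreases with salt included 26 of 41 early stress transcription factors. Decreases were led by RRTF1 (81.1-fold, above background on 2 of 3 salt arrays), DDF1 (41.1-fold, on 2 of 3) and DDF2 (34.6-fold, on 1 of 3). ORA47 (25.6-fold, log2 -4.68 ± 0.65, adjusted p = 0.00113), ERF6, an ethylene-response factor (21.8-fold, log2 -4.45 ± 0.32, adjusted p = 1.77e-05), and the mitochondrial dicarboxylate carrier DIC2 (18.4-fold) fell too. Named increases were those of the beta-glucosidase DIN2 (13.5-fold, water probe above background on 1 of 3 arrays), GA2OX7, which inactivates gibberellins (at least 4.58-fold), and GLYI7 (7.34-fold). Also higher were the hydroxyjasmonate sulfotransferase ST2A (7.33-fold, on 2 of 3), the receptor-like kinase ARCK1 (4.58-fold) and the terpene synthase TPS02 (at least 1.1-fold, above background on 2 of 3 salt arrays). Of 41 early stress factors 26 fell (31 fell and 3 rose adjusted over the list alone, median -2.52), with adjusted p = 7.17e-34, and adjusted p = 0.0463 with an estimated correlation. With a fixed slide term 2 of the 41 were lower, with a median of -1.76, and by limma there were 0 called members in the dehydration, auxin and expansin lists. Dehydration effector genes rose in 2 of 24 (3 adjusted over the list alone, median 0.81, or 0.72 at the bound, adjusted p = 0.849 with an estimated correlation), including KIN2 (2.01 ± 0.36). Auxin response genes rose in 4 of 22 (7 adjusted over the list alone, median 0.62, adjusted p = 0.536 with an estimated correlation). Expansins and xyloglucan endotransglucosylases fell in 2 of 24 (3 adjusted over the list alone, median -0.11, or -0.27 with a fixed slide term, adjusted p = 0.774 with an estimated correlation), XTH22 by -3.68 and XTH18 by -2.86. Flower markers had a median of -1.77 with no member called (0 adjusted over the list alone by limma) and adjusted p = 0.774 with an estimated correlation. Their list level ranged from -3.32 in replicate 1 to 1.27 in replicate 2 of the salt plants. Without salt replicate 1 the flower (adjusted p = 0.355) and dehydration (0.756) lists lost the call, and without salt replicate 2 the expansins and xyloglucan endotransglucosylases did (0.148). CYP707A3 changed by -4.16 ± 0.33 and HSFB2B by -1.02 ± 0.15. In the salicylate list the median was 0.15, the mean 0.34 and the test pointed down.

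The SALK line had 603 called genes, 157 higher and 446 lower. The count was 277 and 299 without water replicates 1 and 2, and 391 without salt replicate 3. A limma fit to only these 6 arrays called 0 genes, with 3167 at an unadjusted p under 0.05. Single arrays ended all 6 named increases but that of GA2OX7: DIN2 (water replicates 1 or 2, salt replicates 2 or 3, adjusted p up to 0.116), GLYI7 (water replicates 1 or 2, salt replicates 1 or 2, 0.206), ST2A and TPS02 (any but salt replicate 3, 0.199 and 0.138) and ARCK1 (water replicates 1 or 3, salt replicates 1 or 3, 0.163), as well as the decrease of RRTF1 (water replicate 1, 0.0516).

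**Figure D2:**
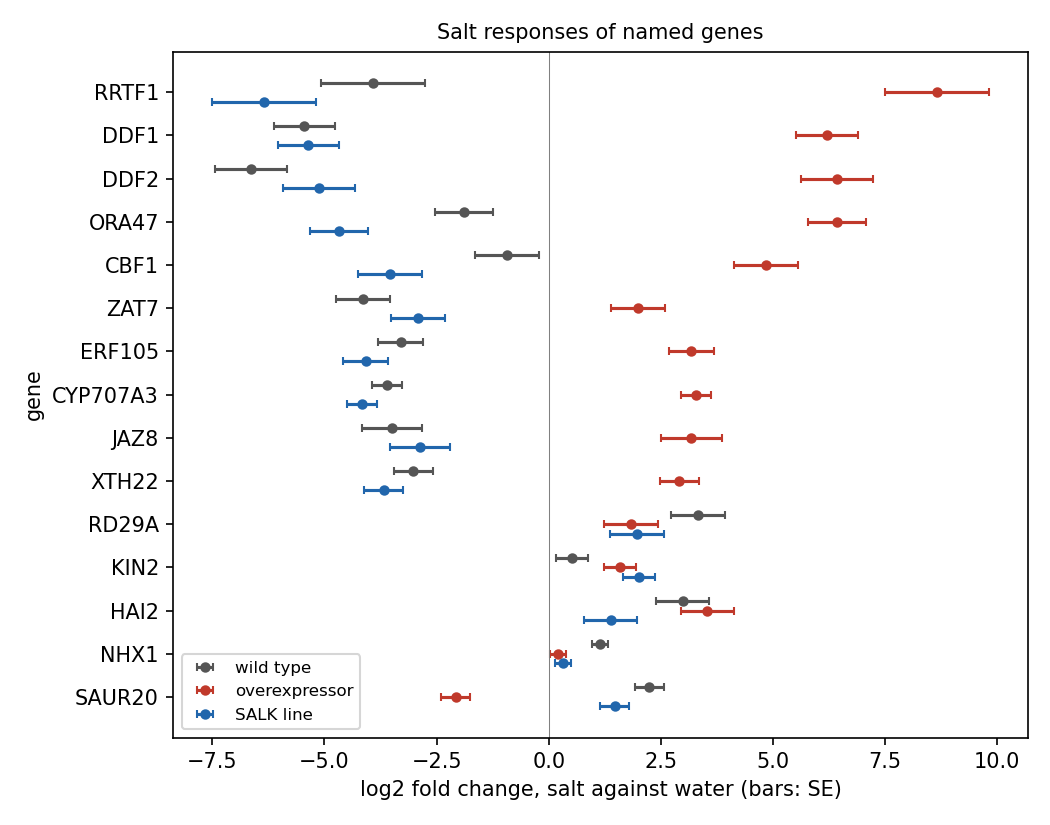
Log2 fold changes of 15 named genes with salt (x axis) in the 3 genotypes; bars are standard errors, and folds of genes not above background in a group are fitted values, not bounds. ORA47 lay at 6.42 in the overexpressor and at -4.68 in the SALK line.

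Whether the salt response differed between genotypes was tested directly, as the salt response of a line minus that of wild type. Genotype and session coincide here too. A salt response that changed with the session, or with the plants or harvests that went with it, cannot be told apart from a genotype effect. For the overexpressor the difference was largest for genes of stress regulation: RRTF1 (at least 3530-fold), DDF1 (at least 2230-fold) and DDF2 (at least 2070-fold). TPPI (log2 8.53 ± 1.74), PHI-1 (8.47 ± 0.74) and ORA47 (8.30 ± 0.92, adjusted p = 5e-05) followed. On the other side were the auxin-induced SAUR63 (-4.51 ± 0.42, adjusted p = 1.26e-05), SAUR20 (-4.31), SAUR29 (-3.56) and SAUR75 (at least 13.4-fold lower). So were the dicarboxylate carrier DIC3 (-4.34) and TSPO (-3.54 ± 0.98). The difference for bHLH112 itself was 1.1 ± 0.24 (adjusted p = 0.0121). Of the 41 early stress transcription factors, 31 had a higher salt response in the overexpressor and none a lower (33 and 0 adjusted over the list alone by limma), with a median difference of 4.15, or 3.99 with dim members at their bound. ERF105 differed by 6.48 ± 0.70. Camera gave adjusted p = 2.5e-34 for this list, and adjusted p = 0.0441 with an estimated correlation. Jasmonate genes differed upwards in 9 of 28 (15 up and 1 down adjusted over the list alone, median 1.27), with JAZ8 at 6.68 and JAZ5 at 4.92. Heat shock genes differed upwards in 3 of 22 (3 adjusted over the list alone, median 1.15), with HSFB2B at 2.96 and HSFB2A at 2.61. With salt this list's median was 0.13 in the overexpressor itself. Without wild type water replicate 1, at a heat shock level of 2.77, the median difference was 0.57 (adjusted p = 0.0184). Expansins and xyloglucan endotransglucosylases differed upwards in 5 of 24 (5 adjusted over the list alone, median 0.49), with XTH18 at 6.33 and XTH22 at 5.93. This list's median was -0.03 with slide as a fixed term, and its call was lost (adjusted p = 0.188). Of 29 class III peroxidases PRX53 differed (3.07 ± 0.64, 1 adjusted over the list alone, list median 0.65). A fixed slide term gave this list a median of 0.25 and 0 called members by limma, and its call was lost (adjusted p = 0.067). Auxin response genes differed downwards in 8 of 22 (9 adjusted over the list alone, median -0.76). These 5 lists were called at the preset correlation and had adjusted p of 0.511, 0.536, 0.511, 0.882 and 0.511 with an estimated correlation. Differing upwards with a fixed slide term were 5 jasmonate, 2 heat shock and 2 expansin or xyloglucan endotransglucosylase genes, and downwards 7 auxin response genes. The peroxidases lost the call without overexpressor water replicate 1 or salt replicate 3, or wild type water replicate 2 or salt replicate 1 (adjusted p up to 0.637). Expansins and xyloglucan endotransglucosylases lost it without overexpressor water replicate 1 (0.0707). The ABA hydroxylases CYP707A3 (6.89 ± 0.47) and CYP707A1 (3.22 ± 0.62) differed upwards, in a list that was not called (median -0.15, mean 0.12), as did GRX480 (4.75) and NAXT1 (3.54). No dehydration effector gene differed by limma's test (0 of 24, with a list median of 0.13, or 0.05 with dim members at their bound and 0.57 with slide as a fixed term).

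The difference was called for 1913 genes, 1122 higher and 791 lower (58.7% higher, against 45.2% after quantile normalization, which moved the median of all genes from -0.02 to -0.12). Without overexpressor water replicate 2 the count was 3723. With slide as a fixed term it was 608, of which the early stress list held 24 and had a median of 4.42. The call of TSPO was lost without any of 10 arrays, that is all but overexpressor water replicate 2 and wild type salt replicate 1 (adjusted p up to 0.102).

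**Figure D3:**
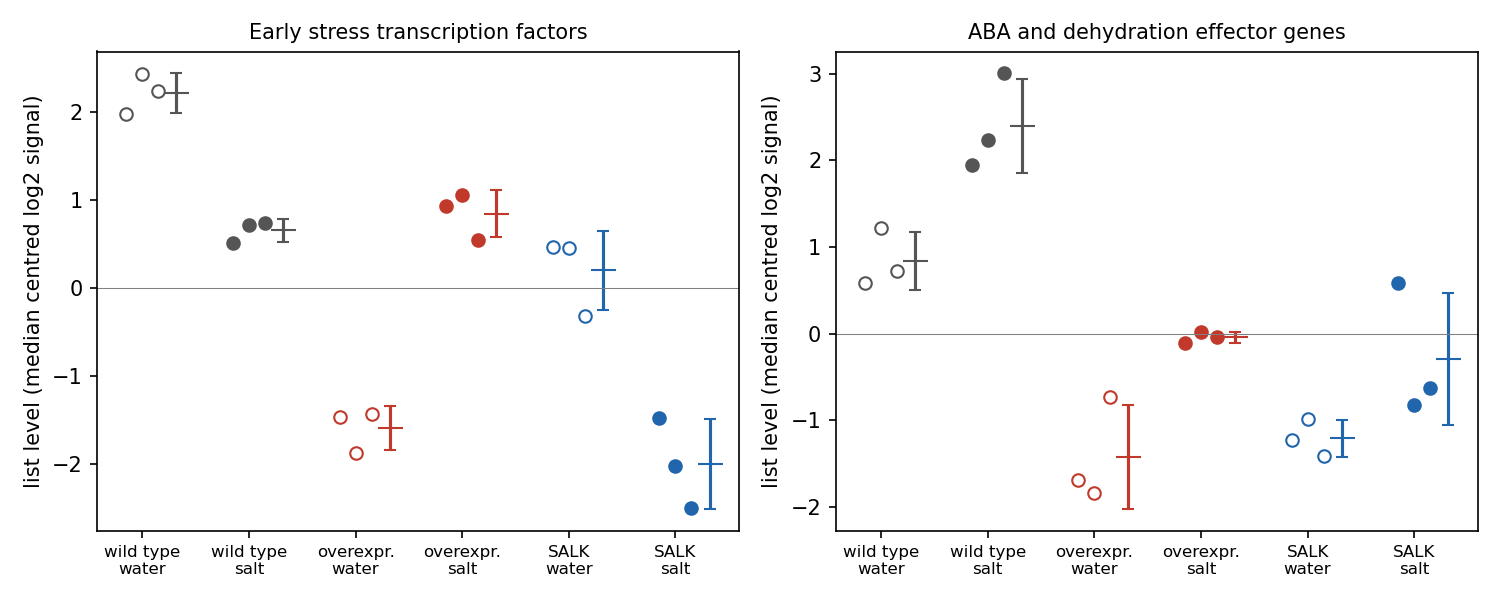
Level of the early stress transcription factors (left) and of the ABA and dehydration effector genes (right) on each array: y axis, median over the list of log2 signals centred per gene; x axis, the 6 groups. Points are arrays, bars the mean and SD; the early stress level was -1.59 in water and 0.85 in salt in the overexpressor, against 2.22 and 0.66 in wild type.

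For the SALK line the difference from the wild type salt response was called for 43 genes, 32 higher and 11 lower. Named increases were BME3, a GATA factor of seed dormancy (1.88 ± 0.25, adjusted p = 0.00769), RPN12b, a proteasome subunit gene (1.75 ± 0.21, adjusted p = 0.00684), the ABA receptor PYL5 (1.83 ± 0.32), HIPP27, a heavy-metal-associated protein (1.81), and BCP1 and ATGA2OX3, for which no bound can be given because 3 of their 4 groups were not above background. Named decreases were NIG1 (-3.82 ± 0.50, adjusted p = 0.00769), CBF3 (-3.33 ± 0.46), the kinase WAG1 (-1.63), PPCK1, a phosphoenolpyruvate carboxylase kinase (-1.53), and HAT22 (-1.1). List tests were called for heat shock genes (median 1.54), early stress factors (-0.45), dehydration effector genes (-0.85, or -0.99 at the bound), ABA synthesis and core signalling (-0.38) and flower markers (-0.93). Each had adjusted p = 0.744 with an estimated correlation, and limma called 0, 1, 0, 1 and 0 of their genes. Adjusted over the list alone, these were 2 higher, 1 lower, 0, 2 higher with 4 lower, and 0. Early stress factors had a median of 0.13 and dehydration effector genes of -0.05 with slide as a fixed term, and both tests turned upwards (adjusted p = 0.695 and 0.658). By limma 0 members of these 5 lists were then called. ABA synthesis and core signalling then lost its call (adjusted p = 0.213), and the flower median was -1.92. Flower markers lost their call with quantile normalization (0.059). Without wild type water replicate 1, at a heat shock level of 2.77, the heat shock median was 0.63 (adjusted p = 0.00895). Leaving out 1 array ended the calls of the dehydration genes (7 of the 12 arrays, adjusted p up to 0.337), the flower markers (4 of 12, 0.703), ABA synthesis and core signalling (SALK salt replicate 2 or wild type salt replicate 3, 0.0551) and the early stress factors (SALK salt replicate 3, 0.0688). Of 100 splits that exchanged water and salt arrays within the genotypes, 10 called as many genes as the labels did. The count was 9 to 20 without SALK water replicates 1, 2 or 3, wild type water replicates 2 or 3, SALK salt replicates 2 or 3, or wild type salt replicates 2 or 3. It was 103 and 203 without salt replicate 1 of the SALK line and of wild type. Quantile normalization gave 56.3% higher, against 74.4%. With slide as a fixed term 1 gene was called. Among the named genes BME3, RPN12b and NIG1 kept their calls without any array. CBF3 lost it without wild type water replicate 3 (0.052), WAG1 without that array or SALK water replicate 1 (up to 0.0719), and the other 6 without 9 or 10 of the 12 arrays (up to 0.165).

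How far the salt responses resembled each other was counted over the called genes. Of the 2371 wild type calls, 79.7% had the same sign in the SALK line and 47.5% in the overexpressor. With slide as a fixed term the shares were 91.91% and 18.65%, over the wild type calls of that fit instead of the 2371. Of the overexpressor calls, 31.5% had the same sign in the SALK line. With slide as a fixed term it was 28.42% of the overexpressor calls of that fit. Salt replicates 2 and 3 of the overexpressor lay on slide 2 with water replicates 1 and 2 of the SALK line. Called in both wild type and the SALK line were 53 genes up and 357 down, where independent lists would share 6.24 and 24.3. Wild type and the overexpressor shared 65 genes up and 68 down (34.4 and 35.2 for independent lists), while 302 fell in wild type and rose in the overexpressor (47.1). Between the overexpressor and the SALK line, 294 genes rose in the first and fell in the second, against 15.3 for independent lists. Across all genes, which are not independent replicates, the log2 fold changes correlated at r = 0.441 for wild type and the SALK line, -0.067 for wild type and the overexpressor and -0.256 for the 2 lines. They were 0.516, -0.136 and -0.344 with normexp correction and 0.347, -0.186 and -0.153 with slide as a fixed term. These 3 pairs share no arrays.

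The overexpressor and the SALK line, scanned in 1 session, were compared with each other. In water, the largest increases in the overexpressor included genes of pathogen defence, and 15 of 28 jasmonate and 26 of 41 early stress genes were lower. Higher were CYP71A13, an enzyme of camalexin synthesis (48.2-fold, its SALK probe above background on 1 of 3 arrays), ALD1 (35-fold, on 1 of 3) and FMO1 (29.4-fold, on 2 of 3), both of the pipecolate pathway of systemic resistance. So were the phospholipase PLA2A (23.4-fold, log2 4.55 ± 0.44, adjusted p = 2.48e-05), the defensin PDF1.2A (22.6-fold) and the beta-1,3-glucanase BG3 (21.7-fold). Lower were RRTF1 (at least 354-fold), ORA47 (91.9-fold, log2 -6.52 ± 0.65, adjusted p = 2.99e-05) and the pollen coat genes GRP17 (at least 19.5-fold) and GRP19 (at least 20.4-fold). Also lower were DFR, dihydroflavonol reductase of anthocyanin synthesis (81.5-fold, above background on 1 of 3 overexpressor arrays), and DDF2 (at least 18-fold).

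Of 22 salicylate and pathogen defence genes, 12 were higher and 1 lower in the overexpressor in water (12 and 1 adjusted over the list alone, median 0.84), with PAD3, the last enzyme of camalexin synthesis, at 4.21 ± 0.71. The level of this list was -0.701, 1.301 and 0.945 in overexpressor replicates 1, 2 and 3, and -0.644, -0.669 and -0.993 in those of the SALK line. Early stress factors were lower in 26 and higher in 5 of 41 (27 and 5 adjusted over the list alone, median -1.61, or -1.59 at the bound), with CBF1 at -3.93. Jasmonate genes were lower in 15 and higher in 2 of 28 (15 and 2 adjusted over the list alone, median -1.22), with the storage protein gene VSP1 at -5.12. Expansins and xyloglucan endotransglucosylases were lower in 11 and higher in 3 of 24 (12 and 3 adjusted over the list alone, median -0.92, or -0.86 at the bound, and with a fixed slide term -0.63, where the call was lost with adjusted p = 0.056), with EXPA15 at -3.75 and XTH22 at -2.83. Flower markers were lower in 7 of 12 (8 adjusted over the list alone, median -2.73, or -2.02 at the bound), AP3 at least 11.6-fold. Their median was 0.29 with slide as a fixed term, where limma called 0 of them and the list lost its call (adjusted p = 0.953). It also lost it without overexpressor replicate 2 or SALK replicate 3 (adjusted p up to 0.102). Evening clock genes were higher in 7 of 11 (7 adjusted over the list alone, median 0.67), with PRR5 at 3.43 ± 0.21 and GI at 1.44. Photosynthesis genes were higher in 3 of 42 (0 adjusted over the list alone by limma, median 0.34). Their median was -0.03 with slide as a fixed term, where the test turned downwards (adjusted p = 0.653), and the call was lost without overexpressor replicate 3 (0.0868) and with quantile normalization (0.935). These 7 lists were called at the preset correlation and none with an estimated one (adjusted p = 0.161 for the evening genes, 0.889 for photosynthesis and 0.807 for each of the others). In the fit with a fixed slide term, 8 early stress factors and 5 jasmonate genes were lower and 1 evening clock gene higher, and limma called 0 members of the other 4 lists. In lists that were not called, the ABA receptors PYL6 (4.40, its SALK probe above background on 1 of 3 arrays) and PYL5 (2.98), the catalase CAT1 (1.83), the transporter gene CAX3 (2.54), the calcium sensor gene SOS3 (1.86) and the clock gene PRR7 (1.21) were higher. CYP707A3 (-3.38), P5CS1 (-2.50) and HSFB2B (-1.75) were lower. In ABA core signalling the median was 0.00, the mean -0.03 and the test pointed up. For heat shock genes the median was 0.01, the mean -0.02 and the test pointed down.

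In water 10490 genes were called, 5102 higher and 5388 lower in the overexpressor, with normexp correction moving the median of all genes from 0.02 to 0.15. The count was 6351 without overexpressor replicate 3 and 2855 in a fit of only these arrays. These groups share no slide. With slide as a fixed term 425 genes were called, with 98% of the calls above keeping their sign. The calls of GRP17 and GRP19 were lost without any array but SALK replicate 2 (adjusted p up to 0.122 for both).

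In salt, the same 2 lines were compared, and 38 of 41 early stress factors were higher in the overexpressor. The defensin genes PDF1.2A (131-fold, log2 7.03 ± 1.18, adjusted p = 0.00145), PDF1.2c (120-fold), PDF1.2B (log2 6.75) and PDF1.3 (102-fold) led, followed by RRTF1 (53.3-fold) and DDF1 (44.7-fold), both above background on 2 of 3 SALK arrays. Lower were the anthocyanin genes LDOX (14.5-fold), UF3GT (12.7-fold) and AT5MAT (7.88-fold) and DIN2 (9.10-fold), each above background on 2 of 3 overexpressor arrays. So were GA2OX7 (at least 3.70-fold) and THAD, a thalianol-pathway enzyme (at least 1.83-fold, above background on 2 of 3 SALK arrays). Of 41 early stress factors 38 were higher (38 adjusted over the list alone, median 2.88), with CBF1 at 4.45 ± 0.71 and adjusted p = 0.0335 with an estimated correlation. Evening clock genes were higher in 6 of 11 (6 adjusted over the list alone, median 0.63, adjusted p = 0.0206 with an estimated correlation), PRR5 by 3.22 and GI by 1.2. Salicylate and pathogen defence genes were higher in 12 of 22 (12 adjusted over the list alone, median 1.59), with PR5 at 2.77. Jasmonate genes were higher in 10 of 28 (10 adjusted over the list alone, median 0.54), and ABA synthesis and core signalling in 9 of 32 (9 adjusted over the list alone, median 0.26), with CYP707A3 at 4.07 and PYL5 at 1.74. Class III peroxidases were higher in 4 of 29 (4 adjusted over the list alone, median 0.68, or 0.49 at the bound), with PER4 at 2.92 (above background on 1 of 3 SALK arrays) and PRX34 at 1.60. Auxin response genes were lower in 10 and higher in 1 of 22 (10 and 1 adjusted over the list alone, median -0.63), SAUR20 by -2.17 and IAA5 by -1.91. The adjusted p of these 5 lists with an estimated correlation was 0.374, 0.546, 0.288, 0.906 and 0.471. The peroxidases lost their call without overexpressor replicate 3 (median -0.03) or SALK replicates 2 or 3 (adjusted p up to 0.411), and the jasmonate genes without SALK replicate 3 (0.0515). A fixed slide term gave medians of 1.61 for the peroxidases, 0.42 for ABA synthesis and core signalling and 0.28 for the jasmonate genes, which lost their call (adjusted p = 0.661). With it limma called 0 early stress factors (median 2.42), 1 evening clock gene and 0 members of the other 5 lists. XTH22 (3.76), FRO2 (1.33) and CAX3 (2.65) were higher and EXPA5 (-1.62) and LHY (-0.92) lower, in lists that were not called.

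In salt 6423 genes were called, 2804 higher and 3619 lower in the overexpressor. The count was 3742 and 3466 without overexpressor replicates 1 and 2, 2873 without SALK replicate 2 and 2237 in a fit of only these arrays. With slide as a fixed term, where the groups share no slide, 5 genes were called and 99.2% of the calls above kept their sign. Single arrays ended the calls of LDOX and UF3GT (overexpressor replicates 1 or 2, SALK replicates 2 or 3, adjusted p up to 0.0858 and 0.117), AT5MAT (overexpressor replicate 1, SALK replicates 2 or 3, 0.112) and DIN2 (SALK replicate 2, 0.054).

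Comparing each line with wild type was the purpose stated by the labels, but here genotype and scanning session cannot be told apart. Against wild type in water, 13 of 15 morning clock genes were higher and 10 of 11 evening clock and 37 of 41 early stress genes lower in the overexpressor. LHY (95.2-fold, log2 6.57 ± 0.12, adjusted p = 4.11e-13) and CCA1 (88.3-fold), the morning clock regulators, COL2 (61.5-fold), ASE3 (at least 18.1-fold), the aquaporin family gene NIP2;1 (at least 14.9-fold) and XTH31 (41.2-fold) were higher. RRTF1 (at least 1710-fold), DDF1 (at least 627-fold), DDF2 (at least 146-fold), GRP19 (at least 183-fold), GRP17 (at least 140-fold) and the thionin THI2.1 (458-fold, above background on 2 of 3 overexpressor arrays) were lower. Morning clock genes were higher in 13 and lower in 1 of 15 (13 and 1 adjusted over the list alone, median 3.24, adjusted p = 0.179 with an estimated correlation). Evening clock genes were lower in 10 of 11 (10 adjusted over the list alone, median -2.84, adjusted p = 0.00175 with an estimated correlation), among them ELF4 (-6.70) and LUX (-4.99). Early stress factors were lower in 37 of 41 (37 adjusted over the list alone, median -3.86, or -3.82 at the bound). Jasmonate genes were lower in 18 of 28 (18 adjusted over the list alone, median -3.02), with JAZ7 at -7.15 and VSP2 at -7.24, and dehydration effector genes in 17 of 24 (17 adjusted over the list alone, median -2.42, or -1.96 at the bound), with KIN2 at -4.38. With an estimated correlation their adjusted p was 0.179, 0.36 and 0.462. Heat shock genes (13 of 22 lower, HSFB2A by -3.00), auxin response genes (12 lower and 3 higher of 22, GH3.3 by -3.89 and IAA19 by -3.10), class III peroxidases (13 of 29 lower), flower markers (7 of 12 lower, PI by -5.33, list median -3.87, or -2.77 at the bound) and proline genes (6 of 10 lower, ERD5 by -1.99) were also called. They had adjusted p of 0.462, 0.462, 0.511, 0.539 and 0.179 with an estimated correlation and 13, 12 and 3, 10, 8 and 6 members adjusted over the list alone. The wild type heat shock level was 2.77 in replicate 1 and 0.546 and 0.61 in replicates 2 and 3, and this list was not tested without replicate 1. Photosynthesis genes were higher in 34 of 42 (35 adjusted over the list alone, median 0.64, adjusted p = 0.507 with an estimated correlation), LHCB2.3 by 2.66. CYP707A3 (-4.99), GRX480 (-5.59), XTH18 (-5.50), PIP2;4 (-3.27) and AGP14 (-2.73) were lower and NHX2 (1.84) and CAT2 (2.21) higher. In all 14776 genes were called, 7524 of them higher, and normexp correction moved the median of all genes from -0.04 to 0.13.

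In salt the overexpressor again had higher morning and lower evening clock genes than wild type. LHY (83-fold, log2 6.38 ± 0.12), COL2 (72.6-fold), CCA1 (62.6-fold), ASE3 (at least 11.1-fold), XTH31 (24.8-fold) and the homeobox gene WOX2 (17.3-fold) were higher. COR27, a cold- and clock-regulated gene (675-fold, log2 -9.40 ± 0.57), the dirigent gene DIR5 (188-fold), YUC9 of auxin synthesis (175-fold), GRP19 (85.9-fold) and GRP16 (83.9-fold), each above background on 1 of 3 overexpressor arrays, and ELF4 (144-fold) were lower. Morning genes were higher in 14 and lower in 1 of 15 (14 and 1 adjusted over the list alone, median 2.56). Evening genes were lower in 10 of 11 (10 adjusted over the list alone, median -2.46), PRR3 by -5.94 and LUX by -4.83. Auxin response genes were lower in 18 of 22 (18 adjusted over the list alone, median -2.27), SAUR22 by -3.75 and GH3.3 by -3.79. Dehydration effector genes were lower in 18 of 24 (19 adjusted over the list alone, median -2.29), RD29A by -4.13, and jasmonate genes in 9, with 1 higher, of 28 (8 and 0 adjusted over the list alone by limma, median -0.69). Photosynthesis genes were higher in 33 of 42 (35 adjusted over the list alone, median 0.63), LHCB2.3 by 2.69. Of these 6 called lists only the evening genes were called with an estimated correlation (adjusted p = 0.000563, and 0.187, 0.187, 0.439, 0.842 and 0.76 for the morning, auxin, dehydration, jasmonate and photosynthesis genes). Early stress factors were higher in 12 and lower in 10 of 41 (14 and 12 adjusted over the list alone), with ZAT7 at 3.43 and DREB2C at -3.65 (above background on 2 of 3 overexpressor arrays), a median of 0.00, a mean of 0.04 and a test pointing down. HAI1 (-4.49) was lower, and ABA1 (2.40) and WRKY54 (2.25) were higher. In all 12803 genes were called, 6778 of them higher. The call of GRP19 was lost without overexpressor replicates 1 or 3 or wild type replicates 2 or 3 (adjusted p up to 0.0866).

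**Figure D4:**
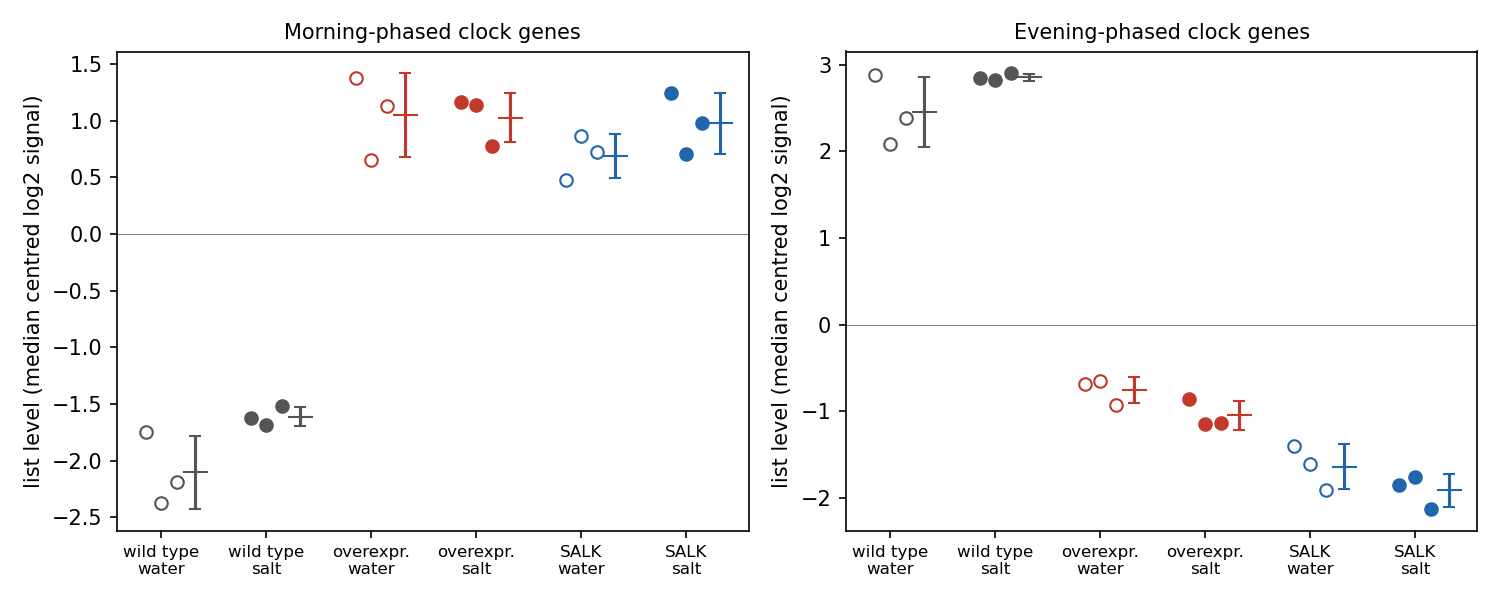
Level of the morning-phased (left) and evening-phased (right) clock genes on each array: y axis, median over the list of log2 signals centred per gene; x axis, the 6 groups. Points are arrays, bars the mean and SD; the evening level was 2.45 in wild type in water, -0.75 in the overexpressor and -1.64 in the SALK line.

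The SALK line differed from wild type in the clock genes in the same directions. In water LHY (149-fold, log2 7.22 ± 0.12), XTH31 (111-fold), NIG1 (89.6-fold), CCA1 (88.5-fold), the B-box gene BBX30 (77.4-fold) and TBL15 (at least 16.5-fold) were higher. COR27 (at least 548-fold), DIR5 (at least 350-fold), ELF4 (231-fold, above background on 1 of 3 SALK arrays), RALFL8 (at least 50.2-fold), BT2 (140-fold) and CYP81D11 (at least 85.5-fold) were lower. Evening genes were lower in 11 of 11 (11 adjusted over the list alone, median -4.70, adjusted p = 0.000515 with an estimated correlation), PRR5 by -5.69. Morning genes were higher in 12 and lower in 1 of 15 (12 and 1 adjusted over the list alone, median 2.99, adjusted p = 0.465 with an estimated correlation). Early stress factors were lower in 36 of 41 (36 adjusted over the list alone, median -2.0, adjusted p = 0.465 with an estimated correlation), DREB2A by -4.41 and NAC019 by -4.99. Dehydration effector genes (17 of 24 lower, KIN2 by -4.00, median -2.28, or -1.80 at the bound), jasmonate genes (15 of 28 lower, JAZ7 by -3.21), salicylate and pathogen defence genes (13 of 22 lower, PAD3 by -4.85), heat shock genes (13 lower and 1 higher of 22, MBF1C by -3.00), auxin response genes (14 lower and 1 higher of 22, GH3.3 by -4.04) and class III peroxidases (13 lower and 1 higher of 29) were called. Each had adjusted p = 0.515 with an estimated correlation, with 17, 15, 13, 13 and 1, 14 and 1, and 12 and 1 members adjusted over the list alone. Here too wild type replicate 1 stood at a heat shock level of 2.77, against 0.546 and 0.61, and the list was not tested without it. Photosynthesis genes were higher in 15 of 42 (13 adjusted over the list alone, median 0.26, adjusted p = 0.771 with an estimated correlation), LHCB2.3 by 2.52. PYL8 (-2.43) and SOS3 (-2.78) were lower and NHX2 (2.52) higher. In all 14911 genes were called, 7725 of them higher.

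In salt LHY (157-fold, log2 7.29 ± 0.12), COL2 (99.2-fold), CCA1 (95-fold), TBL15 (at least 11.5-fold), XTH31 (42.8-fold) and the beta-glucosidase BGLU47 (32.2-fold) were higher in the SALK line than in wild type. COR27 (at least 559-fold), DIR5 (at least 125-fold), CYP81D11 (at least 57.6-fold), and ELF4 (436-fold), the clock regulator PRR3 (117-fold) and the late embryogenesis gene LEA7 (92.2-fold), these 3 above background on 2 of 3 SALK arrays, were lower. Evening genes were lower in 11 of 11 (11 adjusted over the list alone, median -4.82, adjusted p = 0.000264 with an estimated correlation), PRR5 by -5.68. Morning genes were higher in 13 and lower in 1 of 15 (13 and 1 adjusted over the list alone, median 2.34, adjusted p = 0.267 with an estimated correlation). Early stress factors were lower in 37 of 41 (37 adjusted over the list alone, median -2.79), DREB2A by -4.83. Dehydration effector genes were lower in 21 of 24 (22 adjusted over the list alone, median -2.55, or -2.37 at the bound), RAB18 by -4.36. ABA synthesis and core signalling genes were lower in 17, with 6 higher, of 32 (19 and 6 adjusted over the list alone, median -0.70), NCED3 by -3.22 and ABI1 by -2.26. Jasmonate genes were lower in 20 of 28 (22 adjusted over the list alone, median -1.70), AOC3 by -3.60. With an estimated correlation their adjusted p was 0.212, 0.267, 0.267 and 0.321. Salicylate and pathogen defence genes (8 of 22 lower, PAD3 by -4.84), auxin response genes (15 lower and 2 higher of 22), class III peroxidases (10 of 29 lower) and proline genes (4 of 10 lower) were called. They had adjusted p of 0.588, 0.267, 0.588 and 0.212 with an estimated correlation and the same counts adjusted over the list alone. The proline genes lost their call with quantile normalization (adjusted p = 0.0593). Photosynthesis genes were higher in 25 of 42 (28 adjusted over the list alone, median 0.55, adjusted p = 0.618 with an estimated correlation), LHCB2.3 by 2.76. In all 14171 genes were called, 7930 of them higher.

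Genes changed in opposite directions in the overexpressor and the SALK line were counted. In water 272 genes were called in opposite directions against wild type and 10171 in the same direction, where independent calls would give 4373 and 4379. In salt the counts were 179 and 9481 (independent calls 3578 and 3629). Both comparisons use the same wild type arrays. The opposite counts were 1046 in water and 390 in salt with slide as a random block. The covariance of the log2 fold changes was 0.081 in 20 simulations of unchanged water groups sharing the wild type arrays, against 1.44 in the data (0.08 against 1.17 in salt). The simulations held no difference between sessions, which would move both lines in the same direction. Since both lines were scanned in 1 session and wild type in the other, these values cannot tell lines that act alike from a session difference. Opposite changes in salt, higher in the overexpressor and lower in the SALK line, included 9 early stress factors, such as DDF1 (1.83 and -3.65), ERF105 (2.16 and -1.70) and ZAT10 (1.15 and -2.84), as well as CYP707A3 (1.90 and -2.17). In water they included the ABA receptors PYL6 (2.32 and -2.08) and PYL5 (0.64 and -2.34) and, in reverse, P5CS1 (-1.1 and 1.40). The count in water was 1364 and 144 without overexpressor replicates 2 and 3 and 132, 146 and 139 without wild type replicates 1, 2 and 3. In salt it was 114 without overexpressor replicate 2 and 101, 104 and 108 without wild type replicates 1, 2 and 3.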

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

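The tests by other splits of the arrays, the list tests and the fits with slide as a fixed term were chosen before the results were seen. Which of their values to weigh here, and the other tests below, were chosen afterwards. What drew attention to the results of the next paragraphs is a salt response that differed between a line and wild type by a test of the difference itself.

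For the overexpressor minus wild type, the salt responses of 1913 genes differed. The named genes with a higher response in the overexpressor, as log2 differences, were TPPI (8.53), PHI-1 (8.47), ORA47 (8.30), CYP707A3 (6.89), JAZ8 (6.68), ERF105 (6.48), XTH18 (6.33), XTH22 (5.93), JAZ5 (4.92), GRX480 (4.75), NAXT1 (3.54), CYP707A1 (3.22), PRX53 (3.07), HSFB2B (2.96), HSFB2A (2.61) and bHLH112 (1.1). RRTF1, DDF1 and DDF2 were not above background in the overexpressor in water and are given as at least 11.79, 11.12 and 11.02. Their fitted values of 12.57, 11.65 and 13.05 are no measured sizes. Those with a lower response were SAUR63 (-4.51), DIC3 (-4.34), SAUR20 (-4.31), SAUR29 (-3.56), TSPO (-3.54) and SAUR75, not above background in the overexpressor in salt (at the bound -3.75, fitted -4.08). The list medians were 4.15 for early stress transcription factors, 1.27 for jasmonate genes, 1.15 for heat shock genes, 0.65 for class III peroxidases, 0.49 for expansins and xyloglucan endotransglucosylases and -0.76 for auxin response genes. Of these 6 lists only the early stress factors kept their call with an estimated correlation. Without wild type water replicate 1 the heat shock median was 0.57, and with slide as a fixed term that of expansins and xyloglucan endotransglucosylases was -0.03 and that of the peroxidases 0.25. Of 100 splits, 2 gave as many genes, the labels included, and the highest other split gave 2489. That split kept the wild type labels and grouped overexpressor water replicates 1 and 3 with salt replicate 1. The splits exchanged water and salt arrays within each genotype. They thus test for any salt response, not for equal ones, and cannot decide whether chance made the difference.

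For the SALK line minus wild type, the salt responses of 43 genes differed, and chance is not excluded. Of 100 splits, 10 gave as many genes, the highest other 1231. That split kept the wild type labels and set SALK water replicate 3 and salt replicates 1 and 3, all of slide 3, as water. Most SALK arrays then had the exchanged label, so a salt response shared with wild type, or the slides, can raise the count. This count cannot measure chance for the difference. The named genes were BME3 (1.88), PYL5 (1.83), HIPP27 (1.81), RPN12b (1.75), NIG1 (-3.82), CBF3 (-3.33), WAG1 (-1.63), PPCK1 (-1.53) and HAT22 (-1.1). BCP1 and ATGA2OX3 were not above background in 3 of their 4 groups, so their fitted values of 3.64 and 1.99 give neither a size nor a bound. The list medians were 1.54 for heat shock genes, -0.93 for flower markers, -0.85 for dehydration effector genes, -0.45 for early stress transcription factors and -0.38 for ABA synthesis and core signalling. None of these 5 lists kept its call with an estimated correlation. The early stress and dehydration medians were 0.13 and -0.05 with slide as a fixed term, and without wild type water replicate 1 the heat shock median was 0.63.

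In the other 9 comparisons the 10 splits of 6 arrays are too few for a share under 0.05. The salt response counted 2371 genes in wild type (highest other split 0, 1 of 10 as large), 1511 in the overexpressor (3253, 2 of 10) and 603 in the SALK line (6, 1 of 10). The overexpressor against the SALK line counted 10490 genes in water (highest other 8) and 6423 in salt (1). Against wild type the overexpressor counted 14776 and 12803 and the SALK line 14911 and 14171, with 0 genes by limma in each other split.

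Of 41 early stress transcription factors 29 rose with salt in the overexpressor, while 24 fell and 1 rose in wild type and 26 fell in the SALK line (adjusted p of the list 0.043, 0.361 and 0.0463 with an estimated correlation). For the overexpressor minus wild type the median difference was 4.42 with slide as a fixed term, against 4.15 without it. The value of 4.42 rests on 1 salt array against 3 water arrays of 1 slide in each genotype. The list levels without a slide term had a standard error of 0.26, which is not that of 4.42. As far as 1 salt array per genotype can show, the slide layout is argued against as the whole cause. It stays open for the size of the fall in the SALK line and of the difference between the lines in salt: the medians were then -1.76 and 2.42, with 2 and 0 genes called by limma, against 26 and 38 without that term. Exchanged water and salt labels in the overexpressor would turn the dehydration effector genes too, yet their median with salt was 1.40 (standard error 0.35). Between the overexpressor and the SALK line, the state of the water plants alone would leave no difference in salt, where the median was 2.88 (standard error 0.33). Against wild type the state of the water plants cannot be told apart from a changed salt response, as the median was -3.86 in water (standard error 0.19) and 0.00 in salt, and session and genotype coincide; a genotype effect stays open and was not tested apart from it.

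The split of the overexpressor arrays that gave 3253 genes set water replicates 1 and 3 with salt replicate 1 against the rest and points to a structure of the samples. It sets 3 of the 4 arrays of slide 1 against the other overexpressor arrays, so it partly follows the slides. These 3 had the weakest signal of the overexpressor arrays (75th percentile 1100 to 1447, against 1677 to 1931). Signal strength stays open. Exchanged labels of water replicate 2 and salt replicate 1 are argued against: the early stress level of water replicate 2 was -1.88, in a group that spanned 0.45, while the salt arrays lay between 0.55 and 1.06. Under this split 32 of 42 photosynthesis genes were lower (median -0.51) and 7 of 29 class III peroxidases higher (1.49).

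Against wild type, 12 to 14 of 15 morning clock genes were higher and 10 or 11 of 11 evening clock genes lower in both lines. A trend of the ratios with probe brightness or GC content is argued against, because the smallest difference between the medians of both lists was 5.18 with such trends removed. The hour of harvest, the plants or the array batch of the later session cannot be told apart from genotype, since 0 genotypes were scanned in both sessions. A shared harvest hour of the session is thus a candidate explanation, and an effect of both lines stays open as well. Within their session the lines also differed in the evening level, -0.75 in water and -1.05 in salt in the overexpressor against -1.64 and -1.91 in the SALK line. Their morning levels were 1.05 and 1.03 against 0.69 and 0.98. Whether the harvest hour differed between the lines was not tested, so it cannot be told apart from genotype in their comparison either.

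The bHLH112 signal of the line labelled overexpressor was not above that of wild type in water. Probes that do not read the transgene may account for it, and the second probe, with a log2 ratio of -0.65, cannot decide this, since the construct is not given in the sources used here. A difference between sessions cannot be told apart either, as 69.95% of all genes differed by at least as much in this comparison. No biological explanation was tested.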

How the results depend on the processing

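The alternatives restricted to 1 slide and the lists without 1 array were chosen after seeing the data. Precision is limited by 3 arrays per group, by the 68.3% to 80.4% of probes well above background and by the slides, on which treatments are unevenly spread. Arrays of the same replicate number did not pair: 6 of 18 were closest to their own number in other groups. Scan date as a block was not run, since it equals wild type against the lines. Arrays of 1 slide correlated at -0.189 in the random block fit. Normexp correction and limma's trend and robust options left all main values they were run on, 31 and 11, on their side of the threshold or within 1.5 times, but normexp and the fixed slide term moved all 3 correlations of salt responses, which kept their signs. Of 257 named genes, 251 kept their call with quantile normalization, 245 without a filter, 214 with only the groups compared, and 58 of 160 with slide as a fixed term, all in the same direction. The cause was not tested for the changes below, apart from those with a fold limit, which can only lower a count.

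With slide as a fixed block (9 residual degrees of freedom) the salt response counted 445 genes in wild type, 373 in the overexpressor and 55 in the SALK line, the overexpressor against the SALK line 425 in water and 5 in salt, and the differences of salt responses 608 and 1. Of the wild type calls of that fit, 18.65% had the same sign in the overexpressor and 91.91% in the SALK line, over another set of genes than in the main fit. Of 44 called lists 31 kept their call, 10 lost it in the same direction, and in 3 the test turned direction: photosynthesis in the overexpressor against the SALK line in water (adjusted p = 0.653), and dehydration effector genes (0.658) and early stress factors (0.695) in the SALK minus wild type difference. Of 82 called lists 4 lost their call with quantile normalization and 1 with normexp. Slide as a random block gave 1046 opposite changes in water and 390 in salt. Within slides 4, 1 and 3 the salt response counted 479, 421 and 88 genes, with 1 array of a treatment against 3 of the other.

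With at least 2-fold the counts were 1376 and 813 for the salt response of wild type and the overexpressor, 8464 and 6516 for the overexpressor against wild type in water and salt, 8732 and 7899 for the SALK line, and 5284 and 2698 for the overexpressor against the SALK line. With only the groups compared they were 237 and 0 for the salt response of the overexpressor and the SALK line (limma, 3167 of the latter at an unadjusted p under 0.05), and 2855 and 2237 for the overexpressor against the SALK line. The authors' values gave 860, 292 and 4046 for the salt responses of both lines and their comparison in salt. The SALK minus wild type difference counted 14 genes with no filter and 12 with the replicate block. With an estimated correlation 5 of 44 list calls within sessions and 4 of 38 against wild type were left.

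The salt response of bHLH112 in the overexpressor was 0.66 with no filter (adjusted p = 0.0599), 0.64 with the authors' values (0.109) and 0.55 with slide as a fixed block (0.397), over a range of 0.0113 to 0.397 in all alternatives. Its difference from wild type in water was -0.36 with quantile normalization (0.0894) and -0.43 with no filter (0.0576), over a range of 0.00814 to 0.191. The difference of its salt responses was 1.22 with slide as a fixed block (0.129, range 0.00472 to 0.129). With the mean of both probes its salt response in the SALK line was -0.13 (0.821, range 0.0846 to 1).

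Leaving out 1 array gave 1248 to 2498 genes for the salt response in wild type, 723 to 4551 in the overexpressor and 277 to 790 in the SALK line. The overexpressor against the SALK line ranged from 6351 to 13246 in water and from 2873 to 7355 in salt, and the differences of salt responses from 1308 to 3723 and from 9 to 203. For bHLH112 the salt response in the overexpressor ranged from 0.52 to 0.78 and the difference from wild type in water from -0.55 to -0.29. The share with the same sign ranged from 36.6% to 53.44% for wild type and the overexpressor, from 73.6% to 85.56% for wild type and the SALK line and from 22.79% to 37.61% for the lines, and opposite changes from 132 to 1364 in water and from 101 to 218 in salt. Of 330 tests of called lists without 1 array, 286 kept the call and 44 lost it, in the same direction.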

Other observations

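The test of the anthocyanin genes below was chosen after the largest decreases had been seen. Because anthocyanin genes were among the largest decreases of the overexpressor against the SALK line, DFR in water and LDOX, UF3GT and AT5MAT in salt, 12 other genes of anthocyanin synthesis and its regulation were listed, of which 11 were measured. In water 10 of the 11 were lower in the overexpressor and 0 higher by limma (median log2 ratio -2.34, standard error 0.33), among them the transport gene TT19 (-5.35), 3AT2 (-5.22), F3'H (-3.53) and the regulator PAP1 (-3.00). In salt 5 of the 11 were lower (median -2.06). With slide as a fixed term the medians were -1.81 in water and -0.73 in salt. These values are consistent with lower anthocyanin gene expression in the overexpressor than in the SALK line in water, a hypothesis formed and tested on the same arrays.

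Flower markers varied between arrays of a group: their level was -2.49, 0.597 and -0.98 in the 3 salt arrays of the overexpressor and -3.32, 1.27 and -0.526 in those of the SALK line (SD 2.31), against an SD of 0.09 in wild type in water. Heat shock genes stood at 2.77 in water replicate 1 of wild type and at 0.546 and 0.61 in replicates 2 and 3.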
